A study of Mus musculus with 10 samples.

How the data were processed

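RNA of LSK bone marrow progenitors, naive splenic B cells and LPS-activated splenic B cells from Usp3 knockout and wild-type mice (strain 129/Ola x FVB, per the labels) was sequenced on a HiSeq2000 after TruSeq library preparation. Naive B cells were obtained by CD43 depletion and sorting for CD19. LPS-activated cells were cultured for 4 days in 50 µg/ml LPS and then sorted. The labels describe 2 independent experiments with pools of 4 mice per genotype, and the 10 libraries fall into 6 groups, of 2 libraries each for LSK and naive B cells and 1 each for LPS-activated cells.

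The authors used TopHat2 2.0.3, HTSeq (version not given) and the genome build mm9, per the submitters' processing notes, which give neither parameters nor the strand setting. The authors deposited log2 values for all 10 libraries, each the log2 of reads per 10,000,000 assigned reads plus 1. The values were turned back to reads per 10,000,000, each library summed to 10,000,000, and all values were whole multiples of 1 read within a tolerance of 0.01, so whole reads could be recovered. The authors also deposited a table for LSK cells with counts per gene, to which 1 was added for genes with a read in either library of a pair, a log2 ratio of knockout to wild type for each same-numbered pair and a p-value for each pair, whose test is not stated. That table is described as the authors deposited it, and no per-sample column was left unused.

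Of 23428 genes, 14099 with at least 10 reads per 10,000,000 in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3. The linear model used log2 of the value plus 5, a trend of the variance on the mean, two-sided tests and Benjamini-Hochberg adjustment over the genes tested at an adjusted p threshold of 0.05. Group means of all 10 libraries were fitted together (4 residual degrees of freedom, median 7.50 with the pooled prior), and the genotype effect across cell types was fitted as cell type plus genotype (6 residual degrees of freedom). edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. Ensembl IDs of the table were matched to an annotation of the reference (99.53% found, 98.49% with the same coordinates). Where several genes share a symbol (710 genes do), the one with the highest mean stands for it. Figures were drawn with matplotlib 3.10.9.

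The same-numbered libraries of LSK and of naive B cells were treated as pairs in a second fit with a replicate term within each cell type (2 residual degrees of freedom), and its values are called paired. That term takes replicate 1 as its reference. In the activation and identity comparisons the paired differences therefore use only the replicate 1 libraries of naive B and LSK cells. The basis is that the labels name 2 independent experiments and number the replicates, and that the authors' LSK table compares same-numbered libraries, although the labels do not state that the number marks the experiment. Deviations from the group means correlated across genes between same-numbered libraries at 0.645 in LSK and 0.561 in naive B cells, and at 0.253 to 0.306 across cell types. The third principal component, with 2.36% of the variance, split the replicate numbers. The unpaired fit had been fixed and stays the reported one. The paired value stands beside a result where it changes the call or moves a count by more than 1.5 times.

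There were 22 gene lists fixed before the data were examined and tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the lists of a comparison. They were stem cell and multipotent progenitor genes (26 of 26 fixed genes measured), lymphoid priming (18 of 18), granulocyte and monocyte precursor (17 of 20), erythroid (19 of 22), megakaryocyte and platelet (14 of 17), T and NK cell (13 of 20), macrophage and dendritic cell (14 of 21), B cell identity (20 of 21), marginal zone B cell (12 of 13), plasmablast (13 of 16), unfolded protein response (18 of 18), class switch recombination (15 of 18), B cell activation and NF-kB target (21 of 22), p53 target (25 of 25), double-strand break response and repair (31 of 31), histone ubiquitin writers and erasers other than Usp3 (27 of 27), cell cycle (31 of 31), interferon response (25 of 25), immediate early and handling stress (20 of 20), Bcl2 family (16 of 18), ribosomal protein (81 of 83) and mitochondrially encoded genes (29 of 37). Y-linked genes and Xist (1 of 6 measured) were kept as a class with no test. camera compares a list with the other genes, and fry tests whether the members of a list move together in 1 direction.

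Genes are named by a rule from the same time. Usp3 comes first. In each tested comparison the 10 largest rises and falls were taken among genes that passed, did not overlap between the groups and had a mean of at least 50 per 10,000,000 in the higher group. Where fewer passed, genes with the smallest unadjusted p under the same conditions were added up to 5 per direction and are given as not passing. For the LPS-activated pair the 10 largest differences in each direction at 100 per 10,000,000 or more were taken. Up to 4 members of each list with the smallest unadjusted p complete the rule. Antibody and T cell receptor segments, Y-linked genes and Xist are left out of the ranking and given as a class. Other genes are named for small counts of calls or for the chromosome 9 and library patterns, and were chosen after their values were seen.

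Alternatives tried were pseudocounts of 1 and 20, no filter and a filter of 50, median-of-ratios and quantile scaling, a robust or untrended spread, each library left out in turn, the libraries of 1 cell type alone, edgeR, DESeq2 and the replicate term. Added after the data were seen were edgeR with the replicate term, leaving out chromosome 9 genes, leaving out immunoglobulin genes before scaling, and the list tests with the replicate term, without chromosome 9 genes and with each library left out. The LPS-activated pair was not tested, since each genotype has 1 library. A library outside the groups of a contrast adds only to its pooled spread, so leaving it out changes no difference.

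The calculation was tested on simulated data of the same design, in which known 2-fold and 4-fold changes were placed. Without a simulated difference between experiments, limma recovered 23.7% of 2-fold and 75.3% of 4-fold changes in LSK cells (13872 genes), 19.6% and 72.7% in naive B cells (13891 genes), 69.0% and 81.4% across cell types (13884 genes) and 2.08% and 32.7% for the interaction (13872 genes). It recovered 39.8% and 77.8% for activation (13698 genes) and 57.1% and 88.8% for cell identity (12612 genes). With a simulated difference between experiments the unpaired fit recovered 0% of both sizes in LSK cells, in naive B cells and for the interaction, and the paired fit 65.3% and 50.0% of 4-fold changes in LSK and naive B cells. That difference had an SD of 0.5 log2 and was added to a spread estimated without a replicate term. The spread already held the real difference between replicates, so these shares do not give the power in these data. Of 200 random lists 5 fell below an unadjusted camera p of 0.05, and 20 of 20 lists of 20 genes shifted by 0.5 log2 were found. The simulated genes varied independently and without a difference between experiments. Lists whose members move together were therefore not tested.

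Between the 2 replicates of a group the chi-square per gene was 26.7 to 44.6, where counting error alone would give about 1, so the spread between libraries limits these comparisons more than depth does. Reads of genes with near-identical copies, such as Rps2, Rps18, Gm13456, Pcna-ps2, D17H6S56E-5, Hspa1a and Hspa1b, and Bcl2a1a, Bcl2a1b and Bcl2a1d, cannot be placed with certainty. Because the strand setting is not given, overlapping genes on opposite strands can share reads.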

Results

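RNA was sequenced from 3 blood cell populations of mice given in the labels as Usp3 knockout and as wild type. Usp3 is a ubiquitin-specific protease that removes ubiquitin from histones H2A and H2B and acts in the DNA damage response. The populations were LSK cells (lineage-negative, Sca-1-positive, Kit-positive bone marrow cells, which hold the blood stem cells and multipotent progenitors), naive B cells of the spleen, and splenic B cells activated in culture for 4 days with 50 µg/ml lipopolysaccharide (LPS), a bacterial product that drives B cells to divide and to secrete antibody. Each library was made from a pool of 4 mice aged 8 weeks. There were 2 libraries per genotype for LSK and for naive B cells and 1 per genotype for LPS-activated B cells, 10 in all.

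The LSK libraries held 11,426,139 and 7,697,875 assigned reads for the wild type and 8,342,578 and 16,630,488 for the knockout. The naive B libraries held 8,373,175 and 10,018,977 for the wild type and 11,678,871 and 11,805,242 for the knockout. The LPS-activated libraries held 15,197,003 for the wild type and 15,060,992 for the knockout. Expression is given as reads per 10,000,000 assigned reads, and differences as log2 with their SE from limma. Cell type accounted for most of the variation, with 72.2% of the variance on the first principal component and 21.8% on the second. Replicates of a group correlated across genes at 0.975 to 0.989, where genes are not independent replicates.

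Usp3 reads were present in every knockout library at levels near those of the wild type. In LSK cells Usp3 stood at 605 ± 18.9 per 10,000,000 in the wild type and 521 ± 50.9 in the knockout (mean ± SD, n = 2 each). In naive B cells it stood at 710 ± 134 and 585 ± 51.4 (n = 2 each). The LPS-activated libraries gave 460 in the wild type (95% exact Poisson interval 426 to 495) and 430 in the knockout (398 to 465), intervals that overlap and cover counting error only. The knockout minus wild type difference was -0.22 in LSK cells (SE 0.16, adjusted p = 1), -0.27 in naive B cells (SE 0.16, adjusted p = 1) and -0.21 across the cell types (SE 0.09, unadjusted p = 0.0447, adjusted p = 0.999). It was negative in 5 of 5 same-numbered pairs, from -0.37 to -0.10. The difference between LSK and naive B cells was 0.05 (SE 0.23, adjusted p = 1). Usp3 (ENSMUSG00000032376) lies on the minus strand of chromosome 9 from 66362444 to 66440949 in the mouse genome build mm9. The annotation gives it 11 transcripts, and the last of the 15 exons of its longest coding transcript holds 3942 of 5607 bases, or 70.3%. The labels do not say which exons the targeted allele lacks, so a count over the whole gene checks the genotype labels little.

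**Figure D1:**
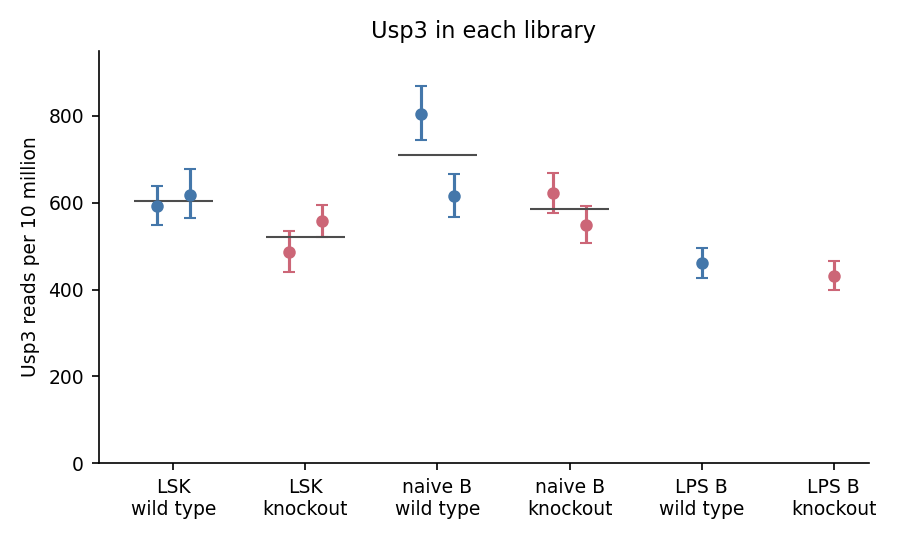
Usp3 reads per 10,000,000 assigned reads in each library, with cell type and genotype on the x axis, wild type in blue and knockout in red. Points are libraries with 95% exact Poisson counting intervals and lines are group means of 2 libraries; knockout means of 521 (LSK) and 585 (naive B) lie beside wild-type means of 605 and 710.

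The LSK comparison asks how loss of Usp3 alters stem and progenitor cells. Erythroid genes were lower in the knockout in 17 of 19 measured members, with a median difference of -1.28. Carbonic anhydrase Car1 stood at 6617 ± 2951 per 10,000,000 in the wild type and 1519 ± 1537 in the knockout (mean ± SD, n = 2 each), a difference of -2.56 (SE 0.83). Klf1, the master regulator of red cell genes, differed by -1.86 (SE 0.62), sphingosine kinase Sphk1 by -2.62 (SE 0.88) and the biliverdin reductase Blvrb by -1.28 (SE 0.34). Genes of lymphoid priming were higher in 14 of 18 members, with a median of 0.45, and genes of the unfolded protein response were higher in 15 of 18, with a median of 0.24. No single gene passed the test over all genes, so these directions rest on the lists.

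As lists, erythroid genes were lower than other genes (camera adjusted p = 5.78e-08; adjusted p = 0.612 with an estimated correlation). Lymphoid priming genes were higher (adjusted p = 0.000317; adjusted p = 0.612 with an estimated correlation). Among them, the genome organiser Satb1 differed by 0.61 (SE 0.18), the cytokine receptor Flt3 by 0.53 (SE 0.19), the repressor Gfi1 by 0.52 (SE 0.25) and the terminal transferase Dntt by 0.77 (SE 0.37). Flt3 stood at 2942 ± 113 in the wild type and 4236 ± 120 in the knockout (n = 2 each). Unfolded protein response genes were higher (adjusted p = 0.000317; adjusted p = 0.297 with an estimated correlation), among them the chaperone Hspa5 at 0.51 (SE 0.23), Creld2 at 0.36 (SE 0.15), Pdia4 at 0.30 (SE 0.16) and Manf at 0.29 (SE 0.15). B cell activation and NF-kB target genes were higher in 16 of 21 members with a median of 0.25 (adjusted p = 0.000317; adjusted p = 0.612 with an estimated correlation), led by the cytokine Tnf at 1.32, Rel at 0.59, Nfkb2 at 0.42 and Nfkbie at 0.39. Interferon response genes were higher in 17 of 25 members with a median of 0.29 (adjusted p = 0.00629; adjusted p = 0.612 with an estimated correlation), with Mx1 at 1.43, Mx2 at 1.37, Oas1a at 0.87 and the RNA sensor Ddx58 at 0.41.

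Cell cycle genes were lower in 30 of 31 members, with a median of -0.18 (camera adjusted p = 0.000317; adjusted p = 0.612 with an estimated correlation). The list median was -0.02 in the replicate 1 pair and -0.33 in the replicate 2 pair, and 18 members were lower in both. Cyclin E1, Ccne1, differed by -1.31 (SE 0.44), the replication licensing genes Cdc6 and Cdt1 by -0.51 and -0.30, and the centromeric histone Cenpa by -0.45. Double-strand break response genes were lower in 26 of 31 members, with a median of -0.20 (adjusted p = 0.00258; adjusted p = 0.612 with an estimated correlation), with Fancd2 at -0.64, the end-joining factor Xrcc5 at -0.47, Rad18 at -0.42 and Mre11a at -0.22. T and NK cell markers were higher in 12 of 13 members (median 0.28, adjusted p = 0.0429; adjusted p = 0.660 with an estimated correlation), with the kinase Lck at 0.63. Marginal zone B cell genes were higher in 10 of 12 (median 0.32, adjusted p = 0.0429; adjusted p = 0.612 with an estimated correlation). The remaining 13 lists did not pass. Stem cell and multipotent progenitor genes had a median of 0.09 (adjusted p = 0.3005), granulocyte and monocyte precursor genes -0.51 (0.121) and megakaryocyte and platelet genes -0.26 (0.195). Macrophage and dendritic cell markers stood at 0.30 (0.1002), p53 target genes at 0.03 (0.315), histone ubiquitin writers and erasers at 0.03 (0.195) and class switch recombination genes at -0.10 (0.406). Bcl2 family genes stood at 0.12 (0.161), mitochondrially encoded genes at 0.00 (0.495) and B cell identity genes at -0.05 (0.597, a test that pointed up). With the libraries treated as paired, 3 further lists passed camera and were higher, namely plasmablast genes (median 0.16, adjusted p = 0.0980, paired 0.00414), immediate early and handling stress genes (0.44, adjusted p = 0.1002, paired 0.000109) and ribosomal protein genes (0.08, adjusted p = 0.1002, paired 0.00394). None of the 3 passed paired with an estimated correlation (adjusted p = 0.582, 0.582 and 0.632). Without LSK knockout replicate 2 the unpaired test pointed the other way for immediate early and ribosomal protein genes, lower in the knockout. Without LSK knockout replicate 1 or LSK wild-type replicate 2 it pointed higher for both.

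**Figure D2:**
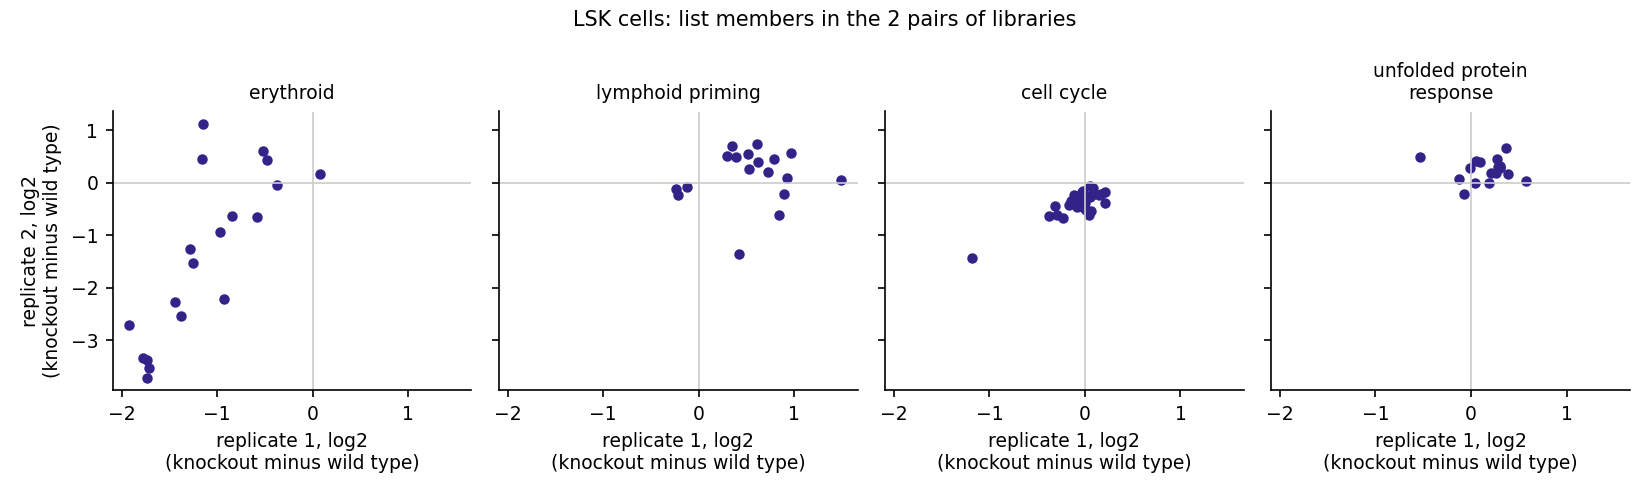
Knockout minus wild type log2 difference of each member of 4 gene lists in LSK cells, with the replicate 1 pair on the x axis and the replicate 2 pair on the y axis. Erythroid genes lie lower in both pairs for 14 of 19 members, lymphoid priming genes higher in both for 12 of 18, unfolded protein response genes higher in both for 12 of 18 and cell cycle genes lower in both for 18 of 31.

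Gene by gene, limma called 0 of 14099 genes in LSK cells, with 592 at an unadjusted p under 0.05 (paired 2551) against 705 expected by chance. edgeR called 0 and DESeq2 called 7, while limma with the libraries treated as paired called 80, 22 higher and 58 lower. Of 499 distinct members of the 22 lists, limma called 0 over all genes, with 36 at an unadjusted p under 0.05 (paired 121). Adjusted over the list alone it called 1, the fatty acid receptor Cd36 at -0.90 (SE 0.19) among the marginal zone genes. edgeR and DESeq2 called 0 of the 499, and the paired fit called 5 over all genes and 75 adjusted over the list alone. The 5 were the transferrin receptor Tfrc (-0.61), Blvrb, the membrane anchor Ank1 (-2.56) and Ccne1, all lower, and the transcription factor Irf4 (0.61), which was higher. The paired list calls included 13 erythroid genes, all lower, 7 unfolded protein response genes, all higher, 8 interferon response genes, all higher, and 7 lymphoid priming genes higher with 1 lower.

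The genes named for the smallest p were, on the lower side, the interferon-induced GTPase Gbp4 (-1.40, SE 0.18, adjusted p = 0.257, paired 0.0241), the myosin Myo1e (-0.999, SE 0.13, adjusted p = 0.257, paired 0.0241), the fatty acid desaturase Scd1 (-1.14, adjusted p = 0.481, paired 0.0241), the glypican Gpc4 (-2.46, adjusted p = 0.628, paired 0.0241) and 1700024P16Rik (-2.52, adjusted p = 0.704, paired 0.0455). Gbp4 stood at 207 ± 1.23 per 10,000,000 in the wild type and 76.0 ± 12.5 in the knockout (n = 2 each). On the higher side they were the lysosomal protease genes Ctsh (1.34, SE 0.20, adjusted p = 0.481) and Lgmn (0.81, adjusted p = 0.865), Haao of tryptophan breakdown (0.81, adjusted p = 0.704, paired 0.0446), the GTPase Rhoq (0.60, adjusted p = 0.865, paired 0.0494) and the adaptor Lat2 (0.85, adjusted p = 0.865, paired 0.0241). Ctsh and Myo1e lie on chromosome 9, as Usp3 does. The 7 DESeq2 calls, chosen here after their values were seen, were Gbp4, Gbp9 (-1.07) and Myo1e, which were lower, and Ctsh, Ms4a6c (1.67) and the antibody segments Ighv1-9 and Ighv6-3, which were higher. Of these 7 the paired fit called Gbp4, Myo1e and Ighv1-9. With no filter limma called 3 genes, Optc, Eya4 and 2610042L04Rik, seen after the values were known and each at a few reads in the wild type alone.

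Within the LSK list results, erythroid and unfolded protein response genes passed camera with each of the 10 libraries left out in turn. Only the LSK libraries among them enter the difference. Without wild-type replicate 1, adjusted p came to 0.129 for cell cycle, 0.385 for double-strand break, 0.146 for NF-kB, 0.241 for T and NK cell and 0.245 for marginal zone genes. Without knockout replicate 2, the cell cycle and double-strand break lists pointed the other way (0.741 and 0.642), and NF-kB, T and NK cell and marginal zone genes did not pass (0.471, 0.741 and 0.0901). Without knockout replicate 1, lymphoid priming (0.356), interferon response (0.552) and marginal zone genes (0.237) did not pass. Without wild-type replicate 2, interferon response (0.924), T and NK cell (0.0582) and marginal zone genes (0.0583) did not pass.

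The authors' own table for LSK cells compares the same-numbered libraries of each pair and gives 4587 genes below a p of 0.05 in the first pair (2305 higher, 2282 lower) and 6254 in the second (2627 higher, 3627 lower). Of 17747 genes tested in both pairs, 1036 were higher in both and 1404 lower in both, against 338 and 463 expected of independent lists, and 420 went opposite ways against 802. Its Car1 log2 ratios were -1.74 and -3.39, and those of the erythroid regulator Gata1 were -0.97 and -0.95. Of the 2429 genes with the same direction in both pairs that were also tested with limma, all had that sign in the limma LSK contrast, 467 with an unadjusted p under 0.05. These are the same libraries, so the overlap is not independent evidence.

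The naive B comparison asks how loss of Usp3 alters resting mature B cells. Unfolded protein response genes were higher in the knockout in 15 of 18 measured members, with a median of 0.21. The chaperone Calr stood at 4549 ± 110 per 10,000,000 in the wild type and 6903 ± 311 in the knockout (mean ± SD, n = 2 each), a difference of 0.60 (SE 0.19). The protein disulphide isomerases Pdia4 and Pdia6 differed by 0.52 (SE 0.16) and 0.37 (SE 0.13) and the chaperone partner Sdf2l1 by 0.55 (SE 0.18). Ribosomal protein genes were lower in 77 of 81 members by a median of -0.18, and marginal zone B cell genes were higher in 10 of 12 by a median of 0.28. No single gene passed over all genes.

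The unfolded protein response list passed camera (adjusted p = 4.91e-08; adjusted p = 0.0738 with an estimated correlation) and was the only list fry called (adjusted p = 0.0220). Marginal zone B cell genes were higher (adjusted p = 0.000202; adjusted p = 0.952 with an estimated correlation), with Asb2 at 0.74, the tetraspanin Cd9 at 0.65, the lipid receptor S1pr3 at 0.49 and the Notch regulator Dtx1 at 0.47. Ribosomal protein genes were lower (adjusted p = 0.000348; adjusted p = 0.952 with an estimated correlation), with Rpl34 at -0.41 and Rpl39 at -0.40. Cell cycle genes were higher in 23 of 31 members with a median of 0.13 (adjusted p = 0.000316; adjusted p = 0.952 with an estimated correlation), with Cdc6 at 1.07, the kinase Aurkb at 0.48 and Mcm7 at 0.26, while Pcna stood at -0.23. T and NK cell markers were lower in 10 of 13 with a median of -0.75 (adjusted p = 0.00532; adjusted p = 0.952 with an estimated correlation), with Tcf7 at -1.76, Cd4 at -1.53, Itk at -0.98 and Nkg7 at -0.96. The mean log2 level of that list was 5.48 in wild-type replicate 1 and 3.98 to 4.17 in the other 3 naive B libraries.

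The unfolded protein response list passed camera with each of the 10 libraries left out in turn, of which only the naive B libraries enter the difference. T and NK cell markers did not pass without wild-type replicate 1, where they pointed up (adjusted p = 0.677), or without knockout replicate 1 (0.192). Ribosomal protein genes pointed up without knockout replicate 1 and without wild-type replicate 2, fits that leave the replicate numbers unbalanced between genotypes. Within the same-numbered naive B pairs, 65 of 81 members were lower in the knockout in both and 2 higher in both. Marginal zone genes did not pass without wild-type replicate 2 (0.902), nor cell cycle genes without knockout replicate 2 (0.780). Erythroid genes had a median of 0.16 (adjusted p = 0.113, paired 0.0295), with the globin genes Hbb-b1 at 1.43 (SE 0.86) and Hba-a1 at 1.46 and the haem synthesis gene Alas2 at 1.05. Mitochondrially encoded genes had a median of -0.13 (adjusted p = 0.268, paired 0.0165), and they passed higher in the knockout without wild-type replicate 2 (0.0108) and lower without wild-type replicate 1 (7.61e-06) or knockout replicate 2 (0.0471). Neither of these lists passed paired with an estimated correlation (adjusted p = 0.786 and 0.946).

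Of the other lists, stem cell genes had a median of -0.03 (adjusted p = 0.555), lymphoid priming genes 0.03 (0.392), granulocyte and monocyte precursor genes -0.04 (0.801) and megakaryocyte genes 0.03 (0.795). Macrophage and dendritic cell markers stood at -0.02 (0.801), B cell identity genes at 0.01 (0.555), plasmablast genes at -0.02 (0.795) and class switch recombination genes at -0.07 (0.998). NF-kB target genes stood at 0.13 (0.268), p53 target genes at -0.01 (0.694), double-strand break genes at -0.03 (0.795) and histone ubiquitin writers and erasers at -0.01 (0.758). Interferon response genes stood at 0.03 (0.348), immediate early and handling stress genes at -0.08 (0.555) and Bcl2 family genes at 0.00 (0.560). For the stem cell, class switch, p53, double-strand break, histone ubiquitin and macrophage lists the test pointed up and the median down, and for lymphoid priming and megakaryocyte genes the mean was below 0 with the median above it. Without wild-type replicate 1, macrophage (0.000129) and granulocyte precursor genes (0.00119) passed as higher, and without wild-type replicate 2 both passed as lower (3.87e-05 and 2.04e-05).

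limma called 0 of 14099 genes in naive B cells, with 324 at an unadjusted p under 0.05 (paired 1760). edgeR called 0, DESeq2 called Smad3, Itih5 and Calr, and the paired limma fit called Smad3, Pde3b and Igj. Of the 499 list members limma called 0 over all genes, with 13 at an unadjusted p under 0.05 (paired 104), and 1 adjusted over the list alone, the anti-apoptotic Bcl2a1a on chromosome 9 (-1.53, SE 0.27), a member of a family of near-identical copies. edgeR called 0 of them, DESeq2 1 (Calr), and the paired fit 1 (Igj) over all genes and 23 adjusted over the list alone. The signal transducer Smad3, on chromosome 9 at 63494574 to 63605801 in mm9, stood at 618 ± 51.0 per 10,000,000 in the wild type and 1251 ± 60.3 in the knockout (n = 2 each), a difference of 1.01 (SE 0.12, adjusted p = 0.338, paired 0.0267). The phosphodiesterase Pde3b differed by 1.17 (SE 0.26, adjusted p = 1, paired 0.0309) and the antibody joining chain Igj by -1.65 (SE 0.95, adjusted p = 1, paired 0.0267). Also higher, without passing either fit, were the thioesterase Acot7 (0.94), the guidance receptor Plxnd1 (0.93) and Stat4 (0.96). Lower were Itih5 (-1.59, SE 0.19, adjusted p = 0.338, paired 0.0509), the amyloid precursor App (-1.26), and 3 genes of chromosome 9, namely the ecto-nucleotidase Nt5e (-1.35), the collagen Col6a4 (-1.83) and the cytoskeletal linker Tln2 (-2.96).

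The genotype effect across the 3 cell types was estimated as 1 additive term. Unfolded protein response genes were higher in 18 of 18 members by a median of 0.18, with Pdia4 and Sdf2l1 at 0.34 (SE 0.11 and 0.12), Calr at 0.30 (SE 0.13) and Creld2 at 0.23 (SE 0.09). The list passed camera (adjusted p = 1.40e-10, and 0.0346 with an estimated correlation, paired 0.186) and fry (adjusted p = 0.0304). It passed with each of the 10 libraries left out in turn. Marginal zone B cell genes were higher in 11 of 12 (median 0.20, adjusted p = 0.000515, and 0.723 with an estimated correlation), with Cd9 at 0.39 and Dtx1 at 0.36. In the LPS-activated pair 10 of 12 were lower. Interferon response genes were higher in 19 of 25 (median 0.18, adjusted p = 0.00217, and 0.776 with an estimated correlation), with Oas2 at 0.86, Mx1 at 0.81 and Rtp4 at 0.57, while the GTPase Iigp1 stood at -1.28. Lymphoid priming genes were higher in 12 of 18 (median 0.09, adjusted p = 0.00217, and 0.723 with an estimated correlation), with Flt3 at 0.40 and Satb1 at 0.39. Their median was 0.03 in naive B cells, and 11 of 18 were lower in the LPS-activated pair.

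Leaving out LSK knockout replicate 1 ended the calls of lymphoid priming (adjusted p = 0.179) and interferon response genes (0.0666), leaving out LSK wild-type replicate 2 or naive B wild-type replicate 1 ended that of interferon response genes (0.0888 and 0.0654), and leaving out naive B wild-type replicate 2 ended that of marginal zone genes (0.0672). With the libraries paired, 5 further lists passed. They were plasmablast (median -0.01, mean 0.06, adjusted p = 0.0881, paired 0.0455) and NF-kB target genes (0.09, adjusted p = 0.0711, paired 0.0193), double-strand break genes (-0.11, adjusted p = 0.0881, paired 0.0455), immediate early and handling stress genes (0.17, adjusted p = 0.193, paired 0.00211) and ribosomal protein genes (-0.06, adjusted p = 0.193, paired 0.0161). None of the 5 passed paired with an estimated correlation (adjusted p = 0.696 to 0.769). Among lists that did not pass, erythroid genes had a median of -0.42 (0.0711), granulocyte precursor genes -0.27 (0.378), megakaryocyte genes -0.14 (0.497), T and NK cell markers -0.17 (0.984) and macrophage markers 0.05 (0.168). Stem cell genes stood at 0.02 (0.168), class switch genes at -0.08 (0.497), cell cycle genes at -0.03 (0.856), mitochondrially encoded genes at -0.07 (0.627) and Bcl2 family genes at 0.02 (0.627). B cell identity genes stood at -0.02 (0.532), p53 target genes at 0.00 (0.734) and histone ubiquitin genes at -0.01 (0.256), and in these 3 the test pointed up. Cell cycle genes passed as higher without LSK knockout replicate 2 (0.00581) and as lower without naive B knockout replicate 2 (0.0230), and T and NK cell markers passed as higher without naive B wild-type replicate 1 (0.0229).

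Gene by gene, the additive limma fit called 0 of 14099, with 548 at an unadjusted p under 0.05 (paired 1589), and edgeR called 0. Of the 499 list members it called 0 both over all genes and adjusted over the list alone, with 31 at an unadjusted p under 0.05 (paired 79), and edgeR, DESeq2 and the paired fit each called 0 over all genes. The zinc finger gene Zfp949, on chromosome 9 at 88442858 to 88465924, was the 1 gene the paired fit called (-1.68, SE 0.23, adjusted p = 0.365, paired 0.00122). Zfp949 stood at 640 ± 25.7 in wild-type and 191 ± 28.9 in knockout LSK cells, at 781 ± 262 and 239 ± 149 in naive B cells (n = 2 each) and at 507 and 197 in the LPS-activated pair. The kinase-related receptor Ryk (-1.15, adjusted p = 0.505), Acpl2 (-1.21, adjusted p = 0.527) and the gamma-secretase component Aph1b (1.49, SE 0.29, adjusted p = 0.851) also lie on chromosome 9. Others named for the smallest p were Tarsl2 (-0.52) and the endocytic receptor Ly75 (-0.34), which were lower, and Plekhg3 (0.40), Dmwd (0.44), Gm13456 (1.98) and the toll-like receptor chaperone Unc93b1 (0.35), which were higher. DESeq2 called 8 genes, Aph1b, Plekhg3, Unc93b1 and C920006O11Rik higher and Zfp949, Ryk, Col6a4 and Gm14706 lower, the last 2 and C920006O11Rik named after their values were seen.

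Genes with a genotype difference were gathered on chromosome 9. Of 96 genes with an unadjusted p under 0.01 in the fit across cell types, 25 lay on chromosome 9, where 5.37 were expected from the 789 tested there, and shuffles of gene positions in runs of 50 reached at most 20 (permutation p = 0.0001, the smallest they can give). Such genes made up 3.17% of tested genes on chromosome 9 and 0.533% elsewhere. They were 4 of 80 genes within 5 Mb of Usp3, 20 of 390 between 5 and 40 Mb (5.13%) and 1 of 318 beyond 40 Mb (0.314%). Of the 25, 19 were lower in the knockout, among them Zfp949, Ryk and Tln2, and 6 higher, among them Smad3 and Aph1b. In the separate tests 13 of 60 such genes lay there in naive B cells (3.35 expected, permutation p = 0.0002) and 12 of 129 in LSK cells (7.21 expected, permutation p = 0.055). With the libraries paired 49 of 349 lay there across cell types (19.5 expected, permutation p = 0.001) and 53 of 513 in naive B cells (28.7 expected, permutation p = 0.002). In LSK cells 58 of 932 lay there with pairing (52.1 expected, permutation p = 0.25), a small excess that did not pass. For the difference between LSK and naive B cells 6 of 51 lay there (2.85 expected, permutation p = 0.075), and 55 of 668 with the libraries paired (37.3 expected, permutation p = 0.005).

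**Figure D3:**
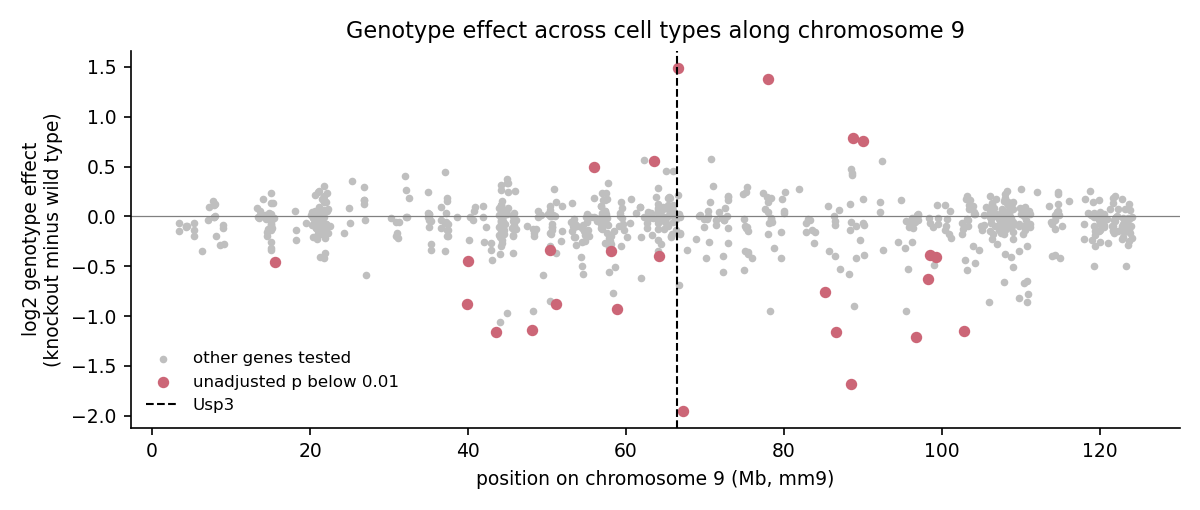
Log2 knockout minus wild type difference across cell types of each tested gene on chromosome 9 (y axis) against its position in Mb of mm9 (x axis). Red points are the 25 genes with an unadjusted p under 0.01, grey points the other tested genes and the dashed line marks Usp3; 24 of the 25 lie within 40 Mb of it.

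Whether the genotype effect differed between LSK and naive B cells was tested as an interaction, LSK minus naive B. Erythroid genes were the most separated list, with all 19 members below 0 and a median of -1.46 (camera adjusted p = 2.48e-09; adjusted p = 0.720 with an estimated correlation). Rhag, a red cell membrane protein, differed by -2.62 (SE 1.19), Sphk1 by -2.64, Car1 by -2.48 and Klf1 by -1.91. Cell cycle genes were below 0 in 29 of 31 (median -0.35, adjusted p = 1.09e-07; adjusted p = 0.720 with an estimated correlation), with Cdc6 at -1.57 (SE 0.38) and Aurkb at -0.72. Double-strand break genes were below 0 in 27 of 31 (median -0.18, adjusted p = 0.00962; adjusted p = 0.720 with an estimated correlation), with Bard1 at -1.15. T and NK cell markers were above 0 in 12 of 13 (median 1.01, adjusted p = 0.000363; adjusted p = 0.720 with an estimated correlation), with Tcf7 at 2.45 and Cd4 at 2.09. Ribosomal protein genes were above 0 in 74 of 81 (median 0.25, adjusted p = 0.000256; adjusted p = 0.720 with an estimated correlation), with Rpl39 at 0.56 and Rpl34 at 0.43.

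Erythroid genes kept their call with each of the 10 libraries left out in turn, of which the LPS-activated libraries do not enter the difference. Without LSK knockout replicate 2 the other 4 lists did not pass, at 0.0561 for cell cycle and for T and NK cell genes, 0.879 for double-strand break genes, which then pointed up, and 0.928 for ribosomal protein genes. Without LSK wild-type replicate 1, double-strand break (0.370) and ribosomal protein genes (0.353) did not pass. The T and NK cell call ended without naive B wild-type replicate 1 (0.201), the ribosomal call without naive B knockout replicate 1 (0.565), and both the ribosomal call, which turned down (0.891), and the double-strand break call (0.0959) without naive B wild-type replicate 2. With the libraries paired, lymphoid priming (median 0.35, adjusted p = 0.0744, paired 0.0408), plasmablast (0.32, adjusted p = 0.167, paired 0.00668), immediate early and handling stress (0.47, adjusted p = 0.0899, paired 0.000365) and mitochondrially encoded genes (0.15, adjusted p = 0.174, paired 0.0409) passed as well, and none of them did paired with an estimated correlation (adjusted p = 0.694 to 0.726).

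The other lists did not pass. Medians were -0.01 for stem cell genes (0.881), -0.40 for granulocyte precursor genes (0.342), -0.19 for megakaryocyte genes (0.262), 0.31 for macrophage markers (0.298), -0.04 for B cell identity (0.787) and -0.04 for marginal zone genes (0.383). They were -0.06 for unfolded protein response genes (0.383), -0.11 for class switch genes (0.567, with a mean of 0.08), 0.29 for NF-kB targets (0.102), 0.09 for p53 targets (0.729), 0.00 for histone ubiquitin genes (0.619), 0.26 for interferon response genes (0.20005) and 0.14 for Bcl2 family genes (0.142). No single gene passed in limma (0 of 14099, 345 at an unadjusted p under 0.05, paired 2122) or edgeR (0), with or without pairing in limma. DESeq2 called 1, the antibody segment Ighv1-9, named after its value was seen. Of the 499 list members limma called 0 over all genes, with 13 at an unadjusted p under 0.05 (paired 134), and edgeR, DESeq2 and the paired fit 0. Adjusted over the list alone limma called 2, Cd36 (-1.16) and Bcl2a1a (1.69), and the paired fit 47. The 10 genes with the smallest p, all at an adjusted p of 1, were the kinase Nek6 (1.63), Haao (0.99), Ms4a6b (1.27), Itih5 (1.29) and Nt5e (1.66) above 0 and Myo1e (-1.05), Smad3 (-0.93), Scd1 (-1.27), the asparagine synthetase Asns (-1.67) and Gbp4 (-1.12) below 0. Nt5e, Myo1e and Smad3 lie on chromosome 9.

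The LPS-activated pair shows how the knockout compares with the wild type after activation, with 1 library each and no test. Among 8634 genes at 100 per 10,000,000 or more in either library, the 2 libraries correlated at 0.991 across genes, which are not independent replicates, and the SD of their log2 differences was 0.199. A difference of 2-fold or more was found for 32 genes, 16 higher and 16 lower in the knockout. Plasmablast genes lay higher in 12 of 13 members with a median of 0.18, with the surface marker Cd93 at 0.98 and Igj at 0.54. NF-kB target genes lay lower in 17 of 21 with a median of -0.24, with the costimulatory receptors Cd86, Cd80 and Cd40 at -0.80, -0.57 and -0.52 and the death receptor Fas at -0.50. p53 target genes lay lower in 24 of 25 with a median of -0.20, with the cell cycle inhibitor Cdkn1a at -0.56 and Eda2r at -0.47.

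Among 10000 random lists of the same size drawn from the tested genes, the median of the plasmablast list ranked at the 100th percentile, those of NF-kB and ribosomal protein genes (-0.12) at 0 and that of p53 targets at 0.005. Interferon response genes (0.12) ranked at 99.95, immediate early and handling stress genes (0.07) at 99.93 and unfolded protein response genes (0.05) at 99.88. B cell identity genes (-0.12) ranked at 0.45, marginal zone genes (-0.17) at 0.5, Bcl2 family genes (-0.13) at 3.8, double-strand break genes (-0.10) at 5.52 and class switch genes (-0.10) at 10.98. The other lists lay between 42.5 and 91.8, with mitochondrially encoded genes lowest, then cell cycle (46.1) and lymphoid priming genes (49.1), T and NK cell markers (63.2), macrophage markers (67.3), megakaryocyte (71.1), erythroid and granulocyte precursor (both 76.2), stem cell (86.8) and histone ubiquitin genes (91.8). These ranks compare genes within 1 pair of libraries and carry no replicate error. The switching deaminase Aicda stood at 284 in the wild type and 175 in the knockout, and Bcl2a1a, on chromosome 9, at 44.1 and 9.96.

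The 10 largest differences upward were the sodium pump subunit Atp1b1 (4.47, from 20.4 to 560 per 10,000,000), D17H6S56E-5 (2.98), Pcna-ps2 (2.65), Prg2 of eosinophil granules (2.25), the class II histocompatibility gene H2-Eb1 (2.24, from 342 to 1631), Rps2 (1.84), Aldh3b1 (1.72), Gm13456 (1.47), Osgin1 (1.31) and the plexin Plxnb2 (1.23). The 10 largest downward were malic enzyme Me1 (-1.63), the chemokine Ccl22 (-1.43, from 4717 to 1747), the macrophage pore protein Mpeg1 (-1.42), Mllt4 (-1.41), Adamts7 (-1.38), Zfp949 (-1.34), Pla2g4b (-1.28), Ms4a4c (-1.25), Serinc3 (-1.24) and Emr1 (-1.24). Me1, Adamts7 and Zfp949 lie on chromosome 9. D17H6S56E-5, Pcna-ps2, Rps2 and Gm13456 have near-identical copies elsewhere in the genome, so their read counts are less certain.

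The activation comparison sets the 2 LPS-activated libraries against the 4 naive B libraries, genotypes together. Plasmablast genes rose in 13 of 13 members with a median of 3.79, among them the secretory regulators Prdm1, from 73.2 ± 15.7 (n = 4) to 6183 ± 691 per 10,000,000 (n = 2), and Xbp1, from 1121 ± 91.5 to 15557 ± 714. Cell cycle genes rose in 30 of 31 with a median of 3.66, and B cell identity genes fell in 17 of 20 with a median of -2.36. The share of reads on immunoglobulin genes was 1.10% to 1.21% in naive B cells and 16.3% and 18.2% in the activated libraries. Of 205 antibody variable, joining and diversity segments tested, 201 rose.

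Prdm1 rose by 6.32 (SE 0.26) and Xbp1 by 3.79 (SE 0.13), Ell2 by 3.31 and Sec11c by 2.42 (list camera adjusted p = 2.57e-09; adjusted p = 0.111 with an estimated correlation). Unfolded protein response genes rose in 15 of 18 members, 16 adjusted over the list alone, with a median of 2.20 (adjusted p = 1.07e-09; adjusted p = 0.0551 with an estimated correlation), led by Pdia6 at 3.48, Creld2 at 3.09, Manf at 3.0045 and Dnajb11 at 2.14. In the cell cycle list (adjusted p = 1.16e-18; adjusted p = 0.202 with an estimated correlation) the nucleotide-producing Rrm2 rose by 5.98, Ccna2 by 5.66, Cdk1 by 5.55 and Ccnb2 by 4.85. p53 target genes rose in 17 of 25 and fell in 2 (median 1.16, adjusted p = 3.87e-05; adjusted p = 0.0853 with an estimated correlation), with Phlda3 at 5.63, Eda2r at 3.90 and Ccng1 at 2.17. Class switch recombination genes rose in 7 of 15 and fell in 1 (median 1.10, adjusted p = 0.0142; adjusted p = 0.202 with an estimated correlation), with Exo1 at 3.58, Polh at 1.64, Ung at 1.14 and Msh6 at 1.10. Double-strand break genes rose in 14 of 31 and fell in 5 (median 0.24, adjusted p = 0.0140; adjusted p = 0.821 with an estimated correlation), with Chek1 at 3.81, Fancd2 at 3.79, Rad51 at 3.68 and Brca1 at 3.28. Bcl2 family genes rose in 8 of 16 and fell in 1 (median 0.65, adjusted p = 0.0135; adjusted p = 0.180 with an estimated correlation), with the survival gene Bcl2l1 at 5.15 and the death genes Bbc3 at 3.04, Bcl2l11 at 1.99 and Bax at 0.81.

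B cell identity genes fell in 17 of 20 and rose in 2 (adjusted p = 3.87e-05; adjusted p = 0.0941 with an estimated correlation), with the complement receptor Cr2 at -4.63, the inhibitory receptor Cd22 at -4.54, Bank1 at -3.86 and Cd37 at -3.42. Marginal zone genes fell in 10 of 12 (median -2.03, adjusted p = 0.00717; adjusted p = 0.560 with an estimated correlation), with Tm6sf1 at -4.05, S1pr3 at -3.42 and Plac8 at -1.91, while Cd36 rose by 3.42. Immediate early and handling stress genes fell in 16 of 20 and rose in 1 (median -2.32, adjusted p = 0.00183; adjusted p = 0.807 with an estimated correlation), with Fosb at -8.07, Fos at -4.55 and Jun at -3.87. Mitochondrially encoded genes fell in 14 of 29 (median -1.04, adjusted p = 0.0135; adjusted p = 0.821 with an estimated correlation), with mt-Rnr2 at -1.96. Of markers of other cell types, macrophage and dendritic cell genes fell in 6 of 14 and rose in 2, with Lyz2 at -3.51 and Csf1r at -3.49 (median -0.65, adjusted p = 0.439). Erythroid genes fell in 6 of 19 and rose in 2 (median -1.47, adjusted p = 0.162, paired 0.0240 and 0.594 paired with an estimated correlation), with Blvrb at -2.90. T and NK cell markers fell in 4 of 13, Lck at -2.03 among them, and rose in 2, Cd28 at 5.13 and Ccl5 at 4.24 (median -0.63, adjusted p = 0.680).

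Of the lists that did not pass camera, NF-kB target genes rose in 6 of 21 and fell in 11 (median -0.38, adjusted p = 0.609), with Cd44 at 2.44, Lta at -4.82 and Cd86 at -2.95. Interferon response genes rose in 6 of 25 and fell in 10 (-0.65, 0.918), with Ifih1 at 2.58, Isg15 at 2.33 and Oas1a at -1.93. Histone ubiquitin writers and erasers rose in 4 of 27 and fell in 12 (-0.29, 0.233), with Usp44 at 4.05 and Cbx7 at -2.30. Stem cell genes rose in 3 of 26 and fell in 1 (0.03, 0.462), with Kit at 3.84. Lymphoid priming genes rose in 5 of 18 and fell in 7 (-0.10 with a mean of 0.05, 0.963), with Ccr9 at 4.56, Flt3 at 3.20 and Bcl11a at -2.82. Granulocyte precursor genes fell in 2 of 17 (-1.05, 0.311), megakaryocyte genes rose in 2 of 14 and fell in 2 (-0.13 with a test that pointed up, 0.963) and ribosomal protein genes rose in 4 of 81 and fell in 12 (-0.23, 0.465).

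**Figure D4:**
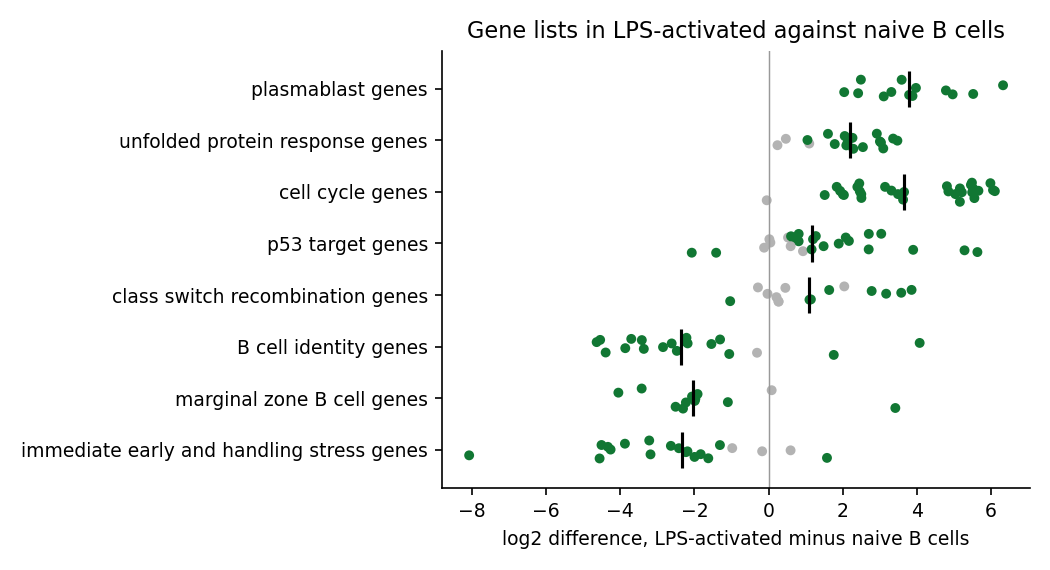
Log2 difference of LPS-activated minus naive B cells (x axis) for each measured member of 8 gene lists (y axis). Green points passed the limma test, grey points did not and black bars mark list medians, which run from -2.36 for B cell identity genes to 3.79 for plasmablast genes.

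Among the 10 largest rises, the chemokine Ccl22 went from 6.81 ± 2.36 (n = 4) to 3232 ± 2100 (n = 2), a rise of 7.95 (SE 0.28), and the interleukin 2 receptor chain Il2ra from 10.03 ± 5.28 to 1821 ± 289, a rise of 6.99. C630004H02Rik (7.30), Sema6d (6.84), the mitotic Hmmr (6.51), the p53 relative Trp73 (6.43), the cell cycle inhibitor Cdkn2a (6.41), Fam46c (6.40, to 13150 per 10,000,000), the inhibitory receptor Ctla4 (6.37) and the signalling regulator Rgs16 (6.36) followed. The 10 largest falls were Fosb, the urokinase receptor Plaur (-6.79), the quiescence factor Klf2 (-6.75, from 5102 ± 685 to 42.3 ± 2.54), Hbb-b1 (-6.60), B3gnt5 (-5.85), Hba-a1 (-5.82), Mapk12 (-5.78), Pglyrp2 (-5.66), Fgr (-5.66) and Dnahc8 (-5.64). Adjusted p for the 20 ran from 2.44e-06 to 5.74e-04. Folds with few reads on 1 side depend on the pseudocount, and in 4 of the 20 that side held at most 2 reads. The ratio of pooled reads per 10,000,000 was 969 for Trp73 (95% exact Poisson interval 268 to 8007, 2 reads in naive B cells), 1866 for Cdkn2a (334 to 73741, 1 read), 1296 for Hbb-b1 (358 to 10702 in the other direction, 2 reads in activated cells) and 764 for Hba-a1 (211 to 6311, 2 reads). These intervals cover counting error only, not the spread between libraries.

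limma called 7878 of 14099 genes between activated and naive B cells, 3351 higher and 4527 lower, or 42.5% higher. Of the 499 list members it called 278 over all genes and 275 adjusted over the list alone, and edgeR called 287. The median of all genes was -0.14, and median-of-ratios rescaling moved it to 0.01, a shift of more than 0.1, and gave 4216 higher and 3678 lower (53.4% higher). Usp3 fell by 0.52 (SE 0.14, adjusted p = 0.0153), a call not kept by DESeq2, edgeR, median-of-ratios or quantile scaling, with immunoglobulin genes left out or without the LPS-activated knockout library. The activated cells had also been cultured for 4 days, which the naive cells had not.

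The identity comparison sets the 4 naive B libraries against the 4 LSK libraries. B cell identity genes were higher in naive B cells in 20 of 20 members, all passing, with a median of 8.85 (camera adjusted p = 2.49e-16; adjusted p = 0.0268 with an estimated correlation, paired 0.274). That paired value compares the replicate 1 libraries only. The surface marker gene Ms4a1 stood at 23276 ± 3990 per 10,000,000 in naive B cells and 12.6 ± 3.99 in LSK cells (mean ± SD, n = 4 each). Stem cell and multipotent progenitor genes were lower in 24 of 26 and higher in 1 (median -6.13, adjusted p = 1.02e-06; adjusted p = 0.547 with an estimated correlation), with Cd34 at 7.25 ± 5.22 against 8282 ± 1642. Cell cycle genes were lower in 31 of 31 (median -4.11, adjusted p = 9.69e-10; adjusted p = 0.547 with an estimated correlation), with Cdk1 at -5.85, Ccnb2 at -5.36 and Mcm6 at -4.11.

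The 10 largest rises were Ms4a1 (10.38, SE 0.19), Cd22 (10.16), the transcription factor Spib (9.9989), Cr2 (9.81), Cd19 (9.62), Faim3 (9.52), the B lineage factor Pax5 (9.29), Bank1 (9.27), Fcer2a (9.19) and Ikzf3 (9.18). The 10 largest falls were the neutrophil enzyme Mpo (-10.06, SE 0.51, from 26683 to 25.5), Gpr56 (-9.47), Cd34 (-9.47), Eltd1 (-9.41), Dntt (-9.0005), the stem cell factor receptor Kit (-8.89), the stem cell regulator Gata2 (-8.86), Angpt1 (-8.72), Muc13 (-8.72) and Atp2b4 (-8.60). Other stem cell genes that fell were Hlf (-8.45), Hoxa9 (-7.16) and Mycn (-6.80). Megakaryocyte genes fell in 13 of 14 and rose in 1 (median -5.10, adjusted p = 0.00134; adjusted p = 0.604 with an estimated correlation), with Itga2b at -6.23 and Gp5 at -5.33. Marginal zone genes rose in 9 of 12 and fell in 2 (median 1.87, adjusted p = 0.000360; adjusted p = 0.547 with an estimated correlation), with Dtx1 at 8.63 and Cd36 at 5.59. NF-kB target genes rose in 13 of 21 and fell in 5 (median 1.53, adjusted p = 0.000305; adjusted p = 0.547 with an estimated correlation), with Cd40 at 8.02 and Nfkb2 at 3.18. Double-strand break genes fell in 22 of 31 and rose in 2 (median -1.12, adjusted p = 0.0139; adjusted p = 0.7996 with an estimated correlation), with Chek1 at -4.95 and Rad51 at -3.61. Mitochondrially encoded genes rose in 11 of 29, 10 adjusted over the list alone (median 0.41, adjusted p = 0.00225; adjusted p = 0.7996 with an estimated correlation).

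The other lists did not pass camera between naive B and LSK cells. Granulocyte precursor genes fell in 9 of 17 and rose in 1 (median -2.59, adjusted p = 0.203), with Ctsg at -8.47, Prtn3 at -8.39 and Elane at -8.05. Erythroid genes fell in 12 of 19 and rose in 5 (-2.72, 0.701), with Gata1 at -6.27. Lymphoid priming genes rose in 8 of 18 and fell in 10 (-0.83, 0.735, a test that pointed up), T and NK cell markers rose in 3 of 13 and fell in 6 (-0.96, 0.972), and macrophage markers rose in 6 of 14 and fell in 8 (-0.98, 0.838, a test that pointed up). Plasmablast genes rose in 6 of 13 and fell in 4 (0.24, 0.154), unfolded protein response genes rose in 2 of 18 and fell in 9 (-0.43, 0.762), class switch genes rose in 2 of 15 and fell in 10 (-0.50, 0.341) and Bcl2 family genes rose in 9 of 16 and fell in 6 (0.61, 0.147). p53 targets rose in 8 of 25 and fell in 12 (-0.35, 0.838), histone ubiquitin genes rose in 8 of 27 and fell in 14 (-0.39, 0.838), and in both the test pointed up. Interferon response genes rose in 5 of 25 and fell in 13 (-1.10, 0.702), immediate early and handling stress genes rose in 2 of 20 and fell in 9 (-0.92, 0.838) and ribosomal protein genes rose in 3 of 81 and fell in 26 (-0.32, 0.705). Of the 205 antibody segments 188 rose and 1 fell.

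limma called 10383 genes between naive B and LSK cells, 3585 higher and 6798 lower, or 34.5% higher. Of the 499 list members it called 364, 363 adjusted over the list alone. The median of all genes was -0.34, and it was -0.05 with median-of-ratios rescaling (46.4% higher) and 0.06 with quantile normalization (51.5% higher), so the balance of rises and falls depends on the scaling. Usp3 was higher in naive B cells by 0.19 without passing (SE 0.12, adjusted p = 0.170). It passed with median-of-ratios (0.48) and quantile scaling (0.49), in edgeR (0.52) and in DESeq2 (0.50). The paired fit, which here compares the replicate 1 libraries only, gave 0.40 (paired 0.00507). In replicate 2, Usp3 stood at 616 and 549 in wild-type and knockout naive B cells and at 618 and 557 in LSK cells. The Y-linked genes and Xist, fixed as a class, held 1 measured gene, Xist, at 6437 to 27999 per 10,000,000 in the 10 libraries, while Y chromosome genes reached at most 2.57.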

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

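In this part the tests on chromosome 9, on the erythroid genes and on plasma cells were chosen after the results were seen, and the rescaling test and the counts over other splits of the libraries were chosen before.

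By camera with its preset correlation the genotype difference was not the same in LSK and naive B cells for 5 gene lists. They were erythroid genes (adjusted p = 2.48e-09), cell cycle genes (1.09e-07), ribosomal protein genes (0.000256), T and NK cell markers (0.000363) and double-strand break genes (0.00962), each at an adjusted p of 0.720 with an estimated correlation. Only erythroid genes kept the call with each library left out in turn. The other 4 lists did not pass without LSK knockout replicate 2, and fry called 0 lists. Among the 4 naive B libraries T and NK cell markers stood highest in wild-type replicate 1, at a mean log2 level of 5.48. Granulocyte and monocyte precursor genes (5.25) and macrophage and dendritic cell markers (5.19) were also highest there. The other naive B libraries reached at most 4.17, 4.27 and 4.71 for the 3 lists. Erythroid genes did not set that library apart, at 6.303 there and 6.296 in knockout replicate 1. The CD43 depletion and CD19 sort would remove most such cells, but how pure each sort was is not known, so carry-over of other cells into that library stays open.

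Genes with an unadjusted genotype p under 0.01 gathered on chromosome 9 around Usp3, with Zfp949, Ryk and Tln2 lower and Smad3 and Aph1b higher in the knockout. Chance position is argued against by the shuffles (permutation p = 0.0001, the smallest they can give). Loss of the Usp3 protein as the only cause is argued against by a share of such genes 5.94 times that elsewhere, where 95% of shuffles gave at most 1.96, and 2.76 in the paired fit, against 1.53. A local effect within 5 Mb is argued against by the 20 genes between 5 and 40 Mb, 39 in the paired fit (permutation p = 0.0001 for each, the smallest they can give). A segment of another strain carried along with the targeted allele may account for the pattern and stays open. Of 12 chromosome 9 genes picked in LSK and naive B cells, 91.7% had the same sign in the LPS-activated pair, against 68.2% of 44 genes elsewhere (Fisher's exact p = 0.149). In the paired fit, genes with an unadjusted p under 0.01 for the difference between LSK and naive B cells also gathered there (55 of 668, permutation p = 0.005).

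Erythroid genes were lower in knockout LSK cells, with Car1 at -2.56, Klf1 at -1.86 and Rhag, Ank1 and Epor lower in both pairs. Haemoglobin-bearing red cell precursors in the wild-type sorts are argued against by the 4 globin genes, which together came to 34.5 per 10,000,000 there, against 8704 and 4530 for Car1. Where the replicate number marks the experiment, an additive difference between the 2 experiments cancels from the contrast by design, with or without the replicate block. The block therefore does not test that cause. The list medians were -1.15 and -1.26 in the 2 pairs, and the list passed with the block (camera adjusted p = 2.29e-08, and 0.314 with an estimated correlation). A smaller share of erythroid-primed cells and a lower level per cell cannot be told apart in RNA of pooled cells. Among 11 members nearly absent from other cells the SD of log2 differences was 0.384 in the replicate 1 pair and 1.05 in the replicate 2 pair, around medians of -1.44 and -2.54, so that 1 factor may describe the first pair and not the second.

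Unfolded protein response genes were higher in the knockout, with Pdia4, Sdf2l1, Calr and Creld2 in the lead. More plasma cells are argued against in naive B cells, where the plasmablast genes had a median of -0.017 and Igj was lower at -1.65. That median lay below the 0.21 of the unfolded protein response genes (exact rank-sum p = 0.00877). The rank-sum test takes genes of the same libraries as independent, so its p carries no error between libraries. Plasma cells stay open in LSK cells, with a plasmablast median of 0.16 and Igj higher in both pairs, although the lineage-negative, Sca-1-positive, Kit-positive gate would remove most of them. They also stay open in the LPS-activated pair, where the plasmablast median of 0.18 lay above the 0.05 of the unfolded protein response genes, as more plasmablasts would give. Rescaling moves all genes of a library nearly alike, so the rescaling test could hardly change the distance of the list from other genes. After median-of-ratios rescaling the list stayed 0.215 above the median of all genes, which decides nothing on scaling. Chance stays open, since 1 of 36 splits of the libraries within cell types, the real one, gave a list median of 0.183 but the highest other gave 0.182, and the 16 splits that part all pairs (highest other 0.158) are too few for a share under 0.05.

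For the genotype effect gene by gene, chance cannot be excluded. As many genes with an unadjusted p under 0.05 as the real 548 came from 13 of 36 splits of the libraries within cell types. The highest other split gave 3543, with 448 called, and it parts no pair. It follows the replicate numbers within cell types rather than the genotypes and points to a structure of the libraries by replicate number. Among the 16 splits that part all 4 pairs, too few for a share under 0.05, the real one gave 548 and the next 347. The paired fit, which takes up the replicate numbers, called 1 gene. For naive B against LSK cells the splits do not test chance, since every other split mixes LSK and naive B libraries in both groups. The cell difference then enters the spread, which leaves few or no calls. Of 35 splits the real one gave 10685 called genes in a fit of 2 groups and the highest other gave 0.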

How the results depend on the processing

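The edgeR fit with the replicate term, the fits without chromosome 9 genes, the scaling without immunoglobulin genes and the list tests with the replicate term, without chromosome 9 genes or with libraries left out were chosen after the results were seen. The count of 0 genes in each of the 4 genotype tests stayed at 0 with pseudocounts of 1 and 20, a filter of 50, both other scalings, robust and untrended spreads, edgeR and each library left out (0 to 0), where the lone library of a group is assumed to vary like the others. In LSK cells no filter gave 3, DESeq2 7, the replicate block 80, edgeR with the block 363 and the block without chromosome 9 genes 34. In naive B cells DESeq2 gave 3, the block 3, edgeR with the block 27 and the block without chromosome 9 genes 2. Across cell types DESeq2 gave 8, the block 1 and edgeR with the block 1, and for the interaction DESeq2 gave 1. In simulated reads with a difference between experiments the paired fit recovered 65.3% of 4-fold and 1.02% of 2-fold changes in LSK cells, where the unpaired fit recovered 0, but neither recovered any for the interaction, and for identity the paired fit recovered 0 where the unpaired fit recovered 54.4% of 4-fold changes. The simulated difference came on top of the real one, so these shares do not give the power in these data. The cause of the paired and DESeq2 counts was not tested. Activation calls ranged from 6238 without the LPS-activated knockout library to 7951, and identity calls from 9441 to 10345.

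With an estimated correlation 0, 0, 1, 0, 0 and 1 lists passed in LSK cells, in naive B cells, across cell types, for the interaction, for activation and for identity, against 9, 5, 4, 5, 11 and 8 with the preset one, and the cause was not tested. fry called 0, 1, 1, 0, 12 and 17, and it pointed down where camera pointed up in the identity comparison for lymphoid priming (adjusted p = 0.0111), p53 target (0.00113) and histone ubiquitin genes (0.000562), as it does not set a list against other genes. The replicate block gave 9 lists across cell types and 9 for the interaction, and 0 in each of the 6 comparisons together with an estimated correlation. With each library left out the lists passing ranged from 5 to 11 in LSK cells, 4 to 8 in naive B cells, 5 to 10 across cell types, 4 to 9 for the interaction, 11 to 13 for activation and 8 to 8 for identity. The replicate block changed the call of no named gene or list other than those given with a paired value or named as called in the paired fit. Usp3 in the interaction turned to -0.05 without LSK knockout replicate 2, to -0.14 without naive B wild-type replicate 1 and to -0.04 without naive B knockout replicate 2, and stood at 0.24 without naive B wild-type replicate 2, none near passing. The chromosome 9 genes left out ended the call of marginal zone genes in LSK cells and no other list call. Alas2 in naive B cells, a gene near the detection limit, turned to -0.29 without knockout replicate 1 and stood at 2.39 without knockout replicate 2. The cause was not tested for either gene. The 32 genes with a 2-fold difference in the LPS-activated pair became 28 to 37 under the other settings. Depth limits genes below about 10 per 10,000,000, which were not tested.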

Other observations

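All values in this part were picked after they were seen, and none carries a test of an explanation. In the paired LSK fit, the 58 genes called lower held the metallothioneins Mt1 (-1.54) and Mt2 (-2.52), the fatty acid ligase Acsl6 (-2.87), malic enzyme Me1 (-1.89), the haem synthesis enzyme Cpox (-1.01), the asparagine synthetase Asns (-1.15) and the folate enzyme Mthfd1 (-0.89), and also the GTPase Gbp8 (-1.68), the cannabinoid receptor Cnr2 (-0.95) and the class II loader H2-DMa (-0.63). None of these passed without pairing. Me1 lies on chromosome 9. Mt1 stood at 573 ± 210 per 10,000,000 in the wild type and 197 ± 87.4 in the knockout (mean ± SD, n = 2 each). The 22 genes called higher in that fit held the nucleic acid sensor Tlr7 (1.31), the leukocyte antigens Cd53 (0.76) and Cd52 (0.70), the interleukin 10 receptor Il10ra (0.76), the B cell factor Pou2f2 (0.68) and Unc93b1 (0.49), which carries Tlr7 to endosomes. No gene group was tested for these picks.

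The class II gene H2-Eb1 varied widely between pools of mice of 1 genotype. In naive B cells it stood at 1582 and 25530 per 10,000,000 in wild-type replicates 1 and 2 and at 5031 and 5727 in the knockout. In LSK cells it stood at 90.1 and 678 in wild-type replicates 1 and 2 and at 24.0 and 60.1 in the knockout. Its neighbour H2-Aa stood at 42585 and 52047 in wild-type and 38148 and 51788 in knockout naive B cells. Rps2, on the same chromosome 17, was also highest in wild-type replicate 2, at 585 in LSK and 574 in naive B cells, against 87.2 to 169 in the other libraries of both cell types. Xist stood at 23088 and 27999 in the replicate 1 LSK libraries and 6659 and 6437 in the replicate 2 libraries, and at 16517 and 18096 against 6743 and 8467 in naive B cells.

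Over 10694 genes with a mean of 50 per 10,000,000 or more, the log2 differences of LSK and naive B cells correlated across genes at 0.0655, which came to 0.341 for 561 genes of chromosome 9 and 0.0438 for the others. Between naive B cells and the LPS-activated pair the values were 0.347 on chromosome 9 and 0.0839 elsewhere, and between LSK cells and the LPS-activated pair 0.230 and 0.00786. Of genes with an unadjusted limma p under 0.05 in LSK cells, 53.6% of 28 on chromosome 9 and 59.3% of 388 elsewhere had the same sign in naive B cells. Genes are not independent replicates, and these values carry no test. Lars2, a gene that gathers reads from mitochondrial ribosomal RNA, took 0.0897% to 1.02% of reads in the 10 libraries.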
